A study of Homo sapiens with 48 samples.

How the data were processed

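The samples were HaCaT keratinocytes transfected with siRNA against MYC, siRNA against TP63 or a non-targeting siRNA, with a control transfection named in the labels for each target. There were 3 biological replicates in each of 4 groups and 4 arrays per extract, 48 arrays in all. Per the labels' protocols, cells received 10 nM of siRNA with the reagent INTERFERin, and total RNA was taken and amplified with T7 polymerase; per the series' design text it was taken 48 hours later. The other channel of each array held RNA of wild-type HaCaT cells. The dose and the time hold for all groups.

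The deposited values are log ratios of both channels of each array, 1 value for each of 22047 probes, with no missing value. The log2 scale of the deposited values was read from the values: 100% of those under 0.1 in size equal the log2 of a ratio with 3 decimals to within 4 decimals, against 21.3% for the natural log and 21.2% for log10. Array medians as deposited lay between -0.01 and 0.03 and array SDs between 0.15 and 0.30. The authors' background correction, normalization and centring are not given in the sources used here and stay unknown. Background and saturation flags and intensities were not used here, so dim spots could not be removed; 12 values exceeded 4 in size, with extremes of -8.41 and 6.99.

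Direction was settled as follows. The MYC siRNA effect on arrays with the sample in Cy3 correlated across probes at r = -0.829 with that on arrays with the sample in Cy5, and the TP63 siRNA effect at r = -0.882, so the deposited ratio runs from 1 fixed dye to the other. It was taken as Cy5 over Cy3, the usual form, and arrays with the sample in Cy3 were turned in sign, so that each value is transfected over reference. It is called likely because MYC is then lower in every MYC siRNA replicate than in every control replicate. TP63 is also lower in every TP63 siRNA replicate, but that difference did not pass the test. The direction of the target values is thus partly a choice and no independent check. The lowest correlation between arrays of the same dye orientation was 0.035.

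Each array's median was subtracted, the Cy3 and the Cy5 arrays of an extract were averaged with equal weight, and the mean counted as 1 replicate, since its 4 arrays share an RNA extract. Genes were named from the platform annotation, which is old: 15227 probes had 1 gene symbol, 0 had several and 6820 are unnamed here. Symbols were updated through synonyms in a RefSeq gene table of assembly GRCh38.p14, which changed 2798 and left 134 that are not current. No coordinates are given, since the annotation names no build. Probes of the same gene were averaged, for 1811 of 12802 genes, and unnamed probes stayed single, which left 19622 features. Probes of the same gene often disagreed in size or direction, among them those of ITGB4, KRT5, LDHA, RPS15, FN1, ITGB1, CCT7, NME1, DST, TXNRD1, EGFR and IQGAP1, so a gene mean can rest on part of its probes.

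Tests used limma 3.58.1 in R 4.3.3 with data.table (version 1.17.8), and figures Python 3.11.15 and matplotlib 3.10.9. A linear model with 4 group means was fitted to the 12 replicate means, with 8 residual degrees of freedom and 2.98 prior degrees of freedom, and contrasts were tested with empirical Bayes moderation and Benjamini-Hochberg adjustment at 0.05. Each knockdown was set against its own control. The difference of both effects, the controls of both experiments and the mean of all controls against the reference were further contrasts. Gene lists fixed before the data were examined, 28 with at least 4 measured members, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, whose p tests whether a list's genes move one way on balance. fry called 21 lists for MYC siRNA and 11 for TP63 siRNA. The reported p63 targets are from general knowledge of the field, not from these samples.

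Named genes follow a rule set before the data were examined: both targets, the 12 largest rises and 12 largest falls of each knockdown among features past adjusted p 0.05 whose 3 knockdown replicates all lay on 1 side of all 3 controls, up to 4 members with the smallest p from each described list, and the 6 largest rises and falls of the other contrasts. With 3 against 3 replicates, 10% of unchanged genes separate in this way by chance. IVL, FST, DKK3 and PTHLH after MYC siRNA, PTHLH after TP63 siRNA, KRT5 and KRT18 after TP63 siRNA and all single probes were chosen after their values were seen.

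On simulated data with 100 features changed by 0.5 and 100 by 1 on the log2 scale among 19622, the MYC comparison recovered 97% and 99% and the TP63 comparison 95% and 100%. The share of false calls was 6.67% and 5.34%, and of 28 lists the shifted list was called and 0 others. The simulated genes varied independently of each other, unlike the genes of a real list. The simulation thus does not show how often camera calls unchanged lists in these data.

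Replicate numbers are shared between each knockdown and its control. Deviations from the group means of same-numbered replicates correlated across features at 0.279, 0.504 and 0.523 in the TP63 experiment, all above 0.1, so there the numbers may pair the samples. This comes from the data, not from the labels, and with 3 replicates per group such a match can arise by chance. Fits with the replicate number as a block were run as alternatives. Ranges of adjusted p given for lists leave out the estimated correlation, which is given beside each list. Replacing single values more than 3 from the median of the 4 arrays of their extract was an alternative chosen after seeing the data. Other alternatives were no median subtraction, scaling by the median absolute deviation, quantile normalization, filters on missing values, each dye swap or dye alone, single probes, robust moderation, only the groups compared, pooled controls, stricter thresholds, all 48 arrays with the extract as a random block, and leaving out each replicate.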

Results

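Gene expression was measured in HaCaT cells, an immortalised human keratinocyte line, 48 hours after transfection with 10 nM of siRNA. There were 4 groups of 3 biological replicates: siRNA against MYC, siRNA against TP63, and for each a control transfection of its own with a non-targeting siRNA. Every extract was hybridised to 4 arrays, with the dyes exchanged, against RNA of untransfected wild-type HaCaT cells, which gave 48 arrays for 12 extracts. The deposited values were log ratios without intensities, so the signal over background of a spot is unknown here, and the precision of each value is limited by the number of arrays. All values below are log2 ratios, and the sign follows the usual Cy5 over Cy3 form, under which MYC is lower after MYC siRNA. It is a likely direction, not one stated by the labels, so the direction of the target values is not independent of it. After averaging the 4 arrays of an extract, replicates of a group correlated across genes between 0.656 and 0.912.

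MYC encodes a transcription factor that drives growth and proliferation, and TP63 encodes p63, a transcription factor of the basal epidermis. MYC mRNA fell by 0.46 (SE 0.088, n = 3 per group; limma, adjusted p = 0.00286) after MYC siRNA. Its log2 ratios to the reference were 0.23, 0.16 and 0.29 in the control replicates and -0.25, -0.29 and -0.16 after MYC siRNA. TP63 mRNA was lower after TP63 siRNA by a smaller amount that did not pass the test (log2 fold change -0.18, SE 0.072, adjusted p = 0.2). Its ratios were -0.07, -0.08 and -0.20 in the TP63 siRNA replicates below 0.06, 0.03 and 0.09 in the controls. It passed when only the 2 groups compared entered the fit (adjusted p = 0.047; range over all alternatives 0.0136 to 0.511). It also passed when all 48 arrays were fitted (adjusted p = 0.0136), but there the estimated correlation between arrays of an extract was 0.0357, so that arrays of 12 extracts counted almost as independent replicates. Both genes had 1 probe each, and what part of the transcripts a probe reads is not given in the sources used here.

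The study addressed whether p63 acts through genes regulated by MYC. MYC mRNA also fell after TP63 siRNA, by 0.43 (SE 0.088, n = 3 per group; limma, adjusted p = 0.0114), from 0.12, 0.01 and 0.45 in the controls to -0.26, -0.26 and -0.21. This call was lost when only the 2 groups compared entered the fit (adjusted p = 0.0623; range over alternatives 1.02e-07 to 0.0623). TP63 mRNA after MYC siRNA differed from its control by 0.04 (SE 0.072, adjusted p = 0.75), which is within the spread between replicates.

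**Figure D1:**
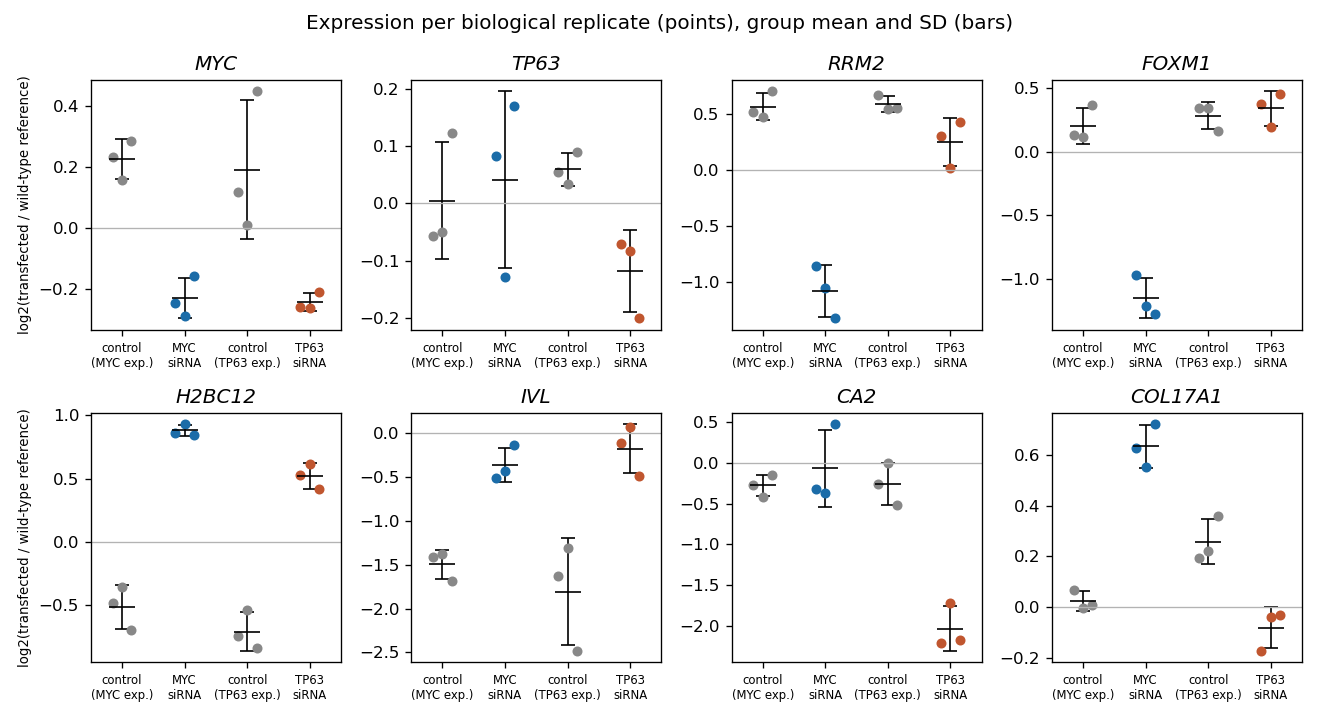
Log2 ratio of transfected over wild-type reference RNA for 8 genes in each of the 12 biological replicates (points), with the group mean and SD (bars); the vertical axes differ between genes. MYC lies below its controls after either siRNA, RRM2 and FOXM1 lie lowest after MYC siRNA, and COL17A1 lies above its controls after MYC siRNA and below them after TP63 siRNA.

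After MYC siRNA, genes of DNA synthesis and cell division fell most. RRM2, a subunit of ribonucleotide reductase, fell by 1.64 (SE 0.12, n = 3 per group; limma, adjusted p = 4.58e-06), and thymidylate synthase TYMS, the replication factor MCM10 and the clamp loader subunit RFC3 fell by 1.51, 1.58 and 1.37. The mitotic genes FOXM1, TPX2, MAD2L1, CEP55, SPAG5, CENPW and ARHGAP11A fell by between 1.34 and 1.41, and the histone gene H4C3 fell by 1.46. The largest rises included other histone genes, with H2BC5 at 1.64 (SE 0.13, adjusted p = 5.34e-06), H2AC6 at 1.53, H2BC12 at 1.39, H2BC15 at 1.27 and H1-2 at 1.20. UBD, a ubiquitin-like modifier, the TNF family ligand TNFSF15, the decoy receptor TNFRSF11B, the collagenase MMP1, the CDK inhibitor CDKN2B, the chloride channel protein CLIC3 and the pregnancy-specific glycoprotein PSG2 rose by between 1.22 and 1.43. Histone genes and pregnancy-specific glycoproteins have near-identical copies that the probes may not separate, so the member named is uncertain.

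Mitosis genes fell almost without exception after MYC siRNA, 36 of 37 measured and 37 adjusted over the list alone, with a median log2 fold change of -0.89 (camera adjusted p = 4.16e-34; adjusted p = 0.0581 with an estimated correlation). CENPA, the centromeric histone, NEK2 and CKS1B fell by 0.94, 1.07 and 1.01. Of 29 DNA replication genes 25 fell, 27 adjusted over the list alone, with a median of -0.67 (camera adjusted p = 1.3e-19; adjusted p = 0.0581 with an estimated correlation). RRM1, the helicase component CDC45 and its partner GINS2 fell by 0.88, 0.66 and 0.68. The CDK inhibitor CDKN1A rose by 0.72 (SE 0.075, adjusted p = 4.72e-05). In all, 4 of the 7 measured CDK inhibitors rose and 1 fell, the same numbers adjusted over the list alone. The list itself was not called (camera adjusted p = 0.0519). Among 21 p53 family members and targets 10 rose and 2 fell, 13 and 2 adjusted over the list alone, including TP53I3 at 0.77 and the antiproliferative gene BTG2 at 0.43 (camera adjusted p = 0.00149; adjusted p = 0.0581 with an estimated correlation).

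Most genes of ribosome biogenesis and of nucleotide synthesis fell with them. Of 26 ribosome biogenesis genes 21 fell, 23 adjusted over the list alone, and none rose, with BOP1 at -0.97, MRTO4 at -0.82 and nucleophosmin NPM1 at -0.57 (camera adjusted p = 1.29e-14; adjusted p = 0.0763 with an estimated correlation). Of 21 nucleotide and polyamine synthesis genes 18 fell, 19 adjusted over the list alone, among them IMPDH2, which makes guanine nucleotides, at -0.88, UMPS at -0.76 and ADSL at -0.76 (camera adjusted p = 1.35e-13; adjusted p = 0.0763 with an estimated correlation). Of 23 genes on the heat shock and chaperonin list, which also holds prohibitins and the peroxiredoxin PRDX3, 17 fell and 2 rose. The numbers were the same adjusted over the list alone, with PRDX3 at -0.62 and prohibitin PHB2 at -0.48. The list was called with the preset correlation (camera adjusted p = 9.23e-07) but not with an estimated one (adjusted p = 0.138). Of 36 cytosolic ribosomal protein genes 11 fell and 1 rose, 11 and 2 adjusted over the list alone, with RPS7 at -0.86 and RPS15 at -0.42 as a mean of probes at -0.78 and -0.07 (camera adjusted p = 0.000673; adjusted p = 0.115 with an estimated correlation). This call was also lost with Cy5 arrays alone (adjusted p = 0.0763; range over alternatives 6.48e-06 to 0.0763). Of 12 aminoacyl-tRNA synthetases 7 fell, FARSB, LARS1 and IARS1 by 0.84, 0.61 and 0.50, while WARS1 rose by 0.57. Of the list 7 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00148; adjusted p = 0.176 with an estimated correlation). Of 19 cholesterol and fatty acid synthesis genes 7 fell, also 7 adjusted over the list alone, including FDPS at -0.41 and MVK at -0.31 (camera adjusted p = 0.00177; adjusted p = 0.219 with an estimated correlation).

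FN1, FERMT2, ITGA3, COL17A1 and MMP1 were among the adhesion and matrix genes that rose after MYC siRNA. Of 26 integrin and focal adhesion genes 17 rose, 19 adjusted over the list alone, and none fell, with FN1, which encodes fibronectin, at 0.70, FERMT2 at 0.69, ITGA3 at 0.60 and ITGB1 at 0.40 (camera adjusted p = 1.21e-06; adjusted p = 0.0763 with an estimated correlation). The probes of FN1 differed in size, at 1.18 and 0.22, as did those of ITGB1, at 0.54, 0.54 and 0.13. Of 17 hemidesmosome and basement membrane genes 9 rose, 10 adjusted over the list alone, including COL17A1 at 0.61 and the laminin chain LAMC1 at 0.38 (camera adjusted p = 1.17e-05; adjusted p = 0.0581 with an estimated correlation). Of 31 genes listed under TGF-beta, matrix and mesenchyme 15 rose and 1 fell, 18 and 1 adjusted over the list alone, with the metalloproteinases MMP1, MMP10 and MMP2 at 1.25, 0.75 and 0.40. This list was also called with an estimated correlation (camera adjusted p = 1.29e-05; adjusted p = 0.0235 with an estimated correlation). Of 29 cell-cell junction genes 9 rose and 4 fell, 9 and 5 adjusted over the list alone, with CLDN1 at 1.16 and E-cadherin gene CDH1 at 0.43. The list was not called (camera adjusted p = 0.164). Of 25 reported p63 targets 9 rose and none fell, 10 rising adjusted over the list alone, including RUNX1 at 0.76 and the Notch ligand JAG1 at 0.55 (camera adjusted p = 0.000458; adjusted p = 0.0581 with an estimated correlation).

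Interferon response genes rose in 24 of 37 cases after MYC siRNA and fell in 1, 27 and 1 adjusted over the list alone, with IFIT2 at 1.15, IFIT1 at 0.49 and TRIM22 at 0.41 (camera adjusted p = 3.43e-09; adjusted p = 0.0763 with an estimated correlation). Of 25 EGFR ligands and inflammatory genes 7 rose, also 7 adjusted over the list alone, including PTGS2 at 0.99 and IL1RN at 0.57 (camera adjusted p = 0.00175; adjusted p = 0.454 with an estimated correlation). The call was lost with quantile normalization (adjusted p = 0.198) and with scaling by the median absolute deviation (adjusted p = 0.0501; range over alternatives 2.19e-08 to 0.198). IL1RN lost its call with the second dye swap alone (adjusted p = 0.0757; range 2.49e-08 to 0.0757). Of 29 epidermal differentiation genes 9 rose and 1 fell, 10 and 1 adjusted over the list alone, with involucrin gene IVL at 1.14, SCEL at 0.85, filaggrin gene FLG at 0.60 and KLK5 at 0.48 (camera adjusted p = 0.0041; adjusted p = 0.132 with an estimated correlation). IVL stayed below the untransfected reference, at -0.51, -0.43 and -0.14 after MYC siRNA against -1.42, -1.38 and -1.69 in the controls. Of 17 Notch pathway genes 3 rose, also 3 adjusted over the list alone (camera adjusted p = 0.0206; adjusted p = 0.132 with an estimated correlation), a call lost without MYC siRNA replicate 3 (adjusted p = 0.0978) and with Cy5 arrays alone (adjusted p = 0.151; range over alternatives 0.00875 to 0.151). Of 10 genes on the fixed histone list 7 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.00447; adjusted p = 0.138 with an estimated correlation). Markers of fibroblasts, melanocytes, immune cells and endothelium were not called, with list medians between -0.01 and 0.04.

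In all, 5273 of 19622 genes and unnamed probes passed limma's test with Benjamini-Hochberg adjustment after MYC siRNA, 2629 higher and 2644 lower. Most changes were small: the median size among them was 0.21, and 448 reached 1.5-fold and 94 reached 2-fold. Of the 28 gene lists 18 were called with camera's preset correlation, against 1 with an estimated correlation, and other groupings of the same 6 replicates gave 7 to 12 called lists. Those groupings mix both groups unevenly and keep part of the real effect, so they do not give the number for unchanged lists. The counts of single genes do not rest on camera's correlation, but 26.9% of all features passed, about as many higher as lower. A list count near that share shows nothing particular to the list. Notch pathway genes passed less often than that, and EGFR ligands and inflammatory genes about as often.

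**Figure D2:**
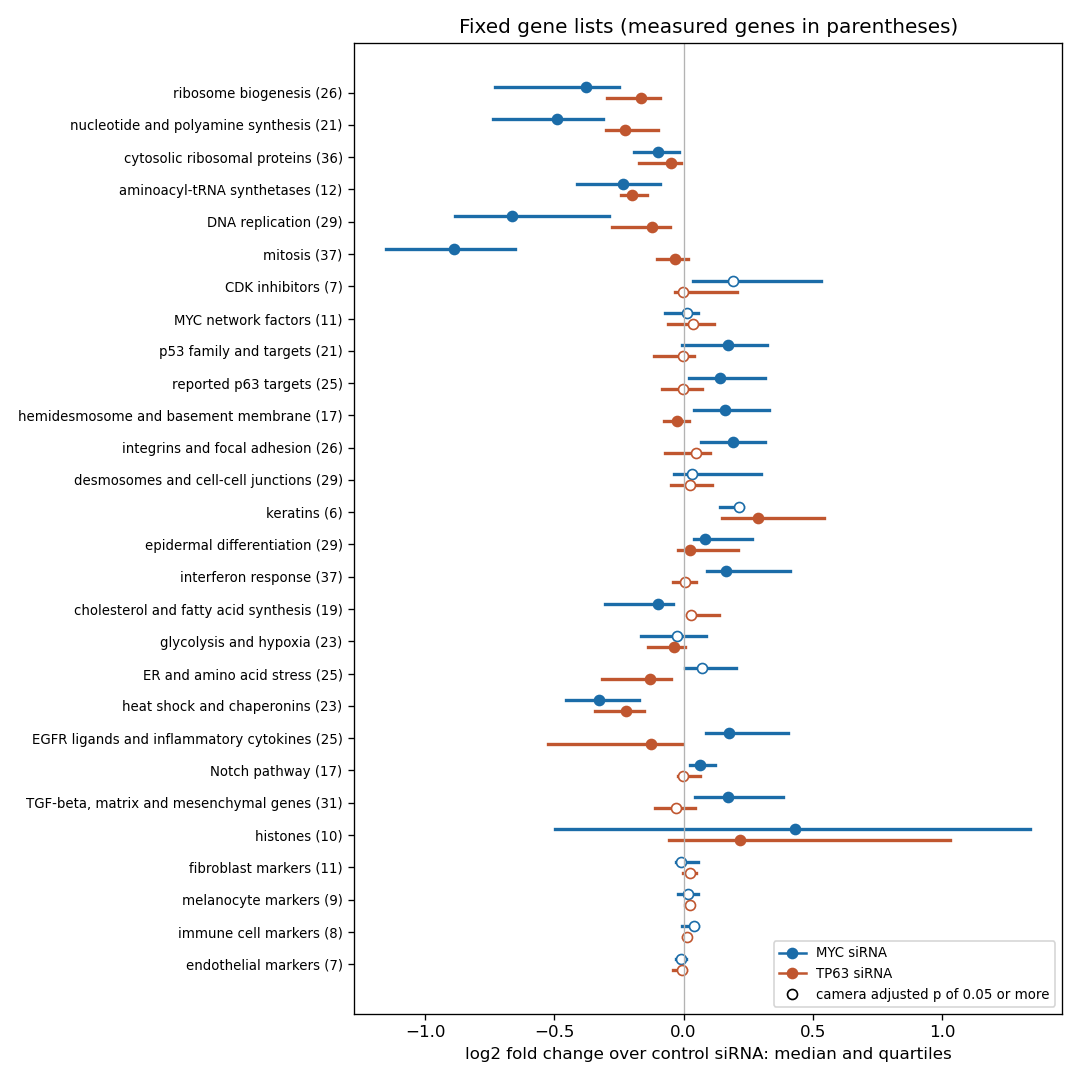
Median (points) and quartiles (lines) of the log2 fold change over control siRNA for the measured genes of each of 28 fixed gene lists, after MYC siRNA and TP63 siRNA; filled points passed camera with its preset correlation. Mitosis genes have a median of -0.89 after MYC siRNA and -0.03 after TP63 siRNA, and ribosome biogenesis genes -0.38 and -0.17.

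After TP63 siRNA, the cornified envelope genes IVL and SCEL were among the largest rises, and CCL2, CA2 and THBS1 had the largest falls. IVL, which encodes the cornified envelope protein involucrin, rose by 1.63 (SE 0.25, n = 3 per group; limma, adjusted p = 0.00232), and SCEL, another cornified envelope gene, rose by 1.40. The rise of IVL was from low controls, at -1.6, -1.3 and -2.5 over the untransfected reference, to -0.1, 0.1 and -0.5. It thus did not rise clearly above untransfected cells, while SCEL did, at 0.85, 0.89 and 0.52. TNFSF15 rose by 1.77 (SE 0.20, adjusted p = 0.000353), and S100A6, FBP1, the long noncoding RNA UCA1, CLIC3, the epithelial transcription factor ELF3 and MAL rose by between 1.15 and 1.41. The histone genes H2AC6, H2BC12 and H2BC5 rose by 1.23, 1.23 and 1.13. The chemokine gene CCL2 fell by 1.84 (SE 0.35, adjusted p = 0.00733), carbonic anhydrase CA2 fell by 1.77 and thrombospondin gene THBS1 fell by 1.37. The activin antagonist FST and the secreted protein DKK3 fell by 1.30 and 1.09, the co-chaperone CHORDC1 by 1.12, the collagen receptor ITGA2 and the protease inhibitor SERPINB2 each by 1.00. TAF11, SMN2, NAP1L1 and DEPDC1B fell by between 0.92 and 0.98; SMN2 has a near-identical copy, so the probe may read either. CHORDC1 lost its call with the second dye swap alone (adjusted p = 0.0559; range over alternatives 3.98e-09 to 0.0559).

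Of 29 epidermal differentiation genes 8 rose and 1 fell after TP63 siRNA, the same numbers adjusted over the list alone, with KLK5 at 1.07 and CEACAM6 at 0.85 beside IVL and SCEL (camera adjusted p = 0.0341; adjusted p = 0.341 with an estimated correlation). This list's call was lost with the second dye swap alone (adjusted p = 0.0955), with Cy5 arrays alone (adjusted p = 0.0829), with pooled controls (adjusted p = 0.0672), with the replicate number as a block (adjusted p = 0.066), without TP63 siRNA replicate 2 (adjusted p = 0.0846) and without replicate 1 of its controls (adjusted p = 0.0857; range over alternatives 0.00372 to 0.0955). Of the 6 measured keratins KRT4, KRT5, KRT7, KRT8, KRT17 and KRT18, which are mostly not basal ones, KRT8 rose by 0.59 (SE 0.038, adjusted p = 1.29e-05), and 4 rose adjusted over the list alone (camera adjusted p = 0.00501; adjusted p = 0.137 with an estimated correlation). The basal keratin KRT5 was not among them, at -0.09 (adjusted p = 0.291), and the list lost its call with single probes (adjusted p = 0.103; range over alternatives 0.000512 to 0.103). The junction genes DSC2, PPL and OCLN rose by 0.90, 0.40 and 0.28, among 5 of 29 that rose, also 5 adjusted over the list alone. OCLN lost its call with Cy3 arrays alone (adjusted p = 0.0608; range over alternatives 4.48e-07 to 0.0608). The list was not called (camera adjusted p = 0.202). On the fixed histone list 7 of 10 genes rose and 1 fell, the same numbers adjusted over the list alone, including H1-2 at 0.70 (camera adjusted p = 4.64e-05; adjusted p = 0.137 with an estimated correlation). The controls of the TP63 experiment were themselves lower for this list than those of the MYC experiment, with a median of -0.20 against 0.22 for the TP63 siRNA effect, while 0 genes passed and 4 were lower adjusted over the list alone (camera adjusted p = 0.00014; adjusted p = 0.441 with an estimated correlation). That call was lost with Cy3 arrays alone (adjusted p = 0.14; range over alternatives 1.43e-05 to 0.14). Against pooled controls the median was 0.16 (adjusted p = 0.00668; range over alternatives 5.79e-06 to 0.00668).

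Of 17 hemidesmosome and basement membrane genes 4 fell after TP63 siRNA, while 4 fell and 3 rose adjusted over the list alone. COL4A1, a basement membrane collagen, fell by 0.90 (SE 0.059, n = 3 per group; limma, adjusted p = 1.29e-05), and ITGA6 and COL17A1, parts of the hemidesmosome, fell by 0.42 and 0.34. Against the pooled controls of both experiments ITGA6 and COL17A1 lost their calls, at -0.25 and -0.22 (adjusted p = 0.227 and 0.0871; ranges over alternatives 3.77e-06 to 0.227 and 3.28e-10 to 0.0871). ITGA6 also lost its call with Cy3 arrays alone (adjusted p = 0.156) and with the second dye swap alone (adjusted p = 0.115). The list was called with the preset correlation (camera adjusted p = 0.0225; adjusted p = 0.323 with an estimated correlation), but not with the first dye swap alone (adjusted p = 0.0799), with Cy5 arrays alone (adjusted p = 0.104), with pooled controls (adjusted p = 0.326), with the replicate number as a block (adjusted p = 0.0774), without TP63 siRNA replicate 2 (adjusted p = 0.106) or without replicate 3 of its controls (adjusted p = 0.133; range over alternatives 0.00844 to 0.326). Among 26 integrin and focal adhesion genes 3 fell and 6 rose, the same numbers adjusted over the list alone, with FERMT1 at -0.38 and FERMT2 at 0.44. The list was not called (camera adjusted p = 0.365). Among 25 EGFR ligands and inflammatory genes 4 fell and 1 rose, 5 and 2 adjusted over the list alone, with EGFR at -0.52 as a mean of probes at -0.69 and -0.34 and IL1RN at 0.82 (camera adjusted p = 0.00529; adjusted p = 0.521 with an estimated correlation), a call lost without replicate 3 of the controls (adjusted p = 0.101; range over alternatives 0.00045 to 0.101). EGFR lost its own call with single probes (adjusted p = 0.0511; range over alternatives 7.55e-11 to 0.0511). Of 25 reported p63 targets 3 fell and 2 rose, the same numbers adjusted over the list alone, and the list was not called (camera adjusted p = 0.365). The Notch ligands JAG1 and DLL1 fell by 0.50 and 0.33, and JAG1 lost its call with Cy3 arrays alone (adjusted p = 0.0843; range over alternatives 5.05e-09 to 0.0843). They were the 2 of 17 Notch pathway genes that fell, while 2 fell and 1 rose adjusted over the list alone, and the list was not called (camera adjusted p = 0.819).

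Some genes of ribosome biogenesis, nucleotide synthesis and protein folding also fell after TP63 siRNA. Of 26 ribosome biogenesis genes 10 fell, 13 adjusted over the list alone, with FBL and RRS1 each at -0.51 and a list median of -0.17 (camera adjusted p = 1.04e-12; adjusted p = 0.158 with an estimated correlation). FBL lost its call with the second dye swap alone (adjusted p = 0.101) and with Cy5 arrays alone (adjusted p = 0.077; range over alternatives 2.78e-05 to 0.101). Of 21 nucleotide and polyamine synthesis genes 5 fell, 13 adjusted over the list alone, including ornithine decarboxylase ODC1 at -0.75, spermine synthase SMS at -0.67 and IMPDH2 at -0.39 (camera adjusted p = 1.8e-09; adjusted p = 0.181 with an estimated correlation). Of 23 genes on the heat shock and chaperonin list 11 fell, while 13 fell and 1 rose adjusted over the list alone. The chaperonin gene CCT2 was at -0.50 and prohibitin PHB2 at -0.31. The list was called with the preset correlation (camera adjusted p = 6.28e-09) but not with an estimated one (adjusted p = 0.181). Of 12 aminoacyl-tRNA synthetases 4 fell, 8 adjusted over the list alone, with IARS1 at -0.44 (camera adjusted p = 1.52e-07; adjusted p = 0.137 with an estimated correlation). Of 36 cytosolic ribosomal protein genes 6 fell, 11 adjusted over the list alone, with RPL13 at -0.36 (camera adjusted p = 0.000112; adjusted p = 0.146 with an estimated correlation). Of 25 genes of ER and amino acid stress 5 fell, 6 adjusted over the list alone (camera adjusted p = 0.000112; adjusted p = 0.494 with an estimated correlation). Asparagine synthetase gene ASNS fell by 0.49, a call lost without TP63 siRNA replicate 1 (adjusted p = 0.0645) and with only the 2 groups compared (adjusted p = 0.0669; range over alternatives 8.86e-10 to 0.0669).

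DNA replication genes fell in 5 of 29 cases after TP63 siRNA, 10 adjusted over the list alone, with RRM1 at -0.32 (camera adjusted p = 3.04e-07; adjusted p = 0.239 with an estimated correlation). Of 37 mitosis genes 3 fell, also 3 adjusted over the list alone, among them KIF23 at -0.83 and cyclin A2 gene CCNA2 at -0.40 (camera adjusted p = 0.0142; adjusted p = 0.602 with an estimated correlation). That call was lost with the first dye swap alone (adjusted p = 0.0799) and with pooled controls (adjusted p = 0.193). It was also lost without TP63 siRNA replicate 2 (adjusted p = 0.716) and without replicate 1 of the TP63 experiment's controls (adjusted p = 0.0857). Over alternatives the adjusted p ranged from 8.73e-05 to 0.716. The list median turned to 0.008 without TP63 siRNA replicate 2 and was -0.014 with pooled controls. With Cy3 arrays alone RRM1 and CCNA2 lost their calls (adjusted p = 0.0615 and 0.0635; ranges over alternatives 2.97e-06 to 0.0615 and 2.23e-06 to 0.102), as CCNA2 did with the second dye swap alone (adjusted p = 0.102). Of 23 glycolysis and hypoxia genes 5 fell and 1 rose, 6 and 2 adjusted over the list alone, including ADM at -0.38 (camera adjusted p = 0.0142; adjusted p = 0.137 with an estimated correlation). With Cy5 arrays alone the list and ADM lost their calls (adjusted p = 0.182 and 0.0642; ranges over alternatives 0.00404 to 0.182 and 4.9e-06 to 0.0642). LDHA, lactate dehydrogenase, fell by 0.80 as a mean of 3 probes that disagreed, at -1.78, -0.53 and -0.08. The MYC partner MAX fell by 0.36, the p53 target TP53I3 rose by 0.42 and the CDK inhibitor CDKN2B rose by 0.93, but none of their lists was called. Of 11 MYC network factors 1 rose and 2 fell, 2 and 2 adjusted over the list alone (camera adjusted p = 0.848). Of 21 p53 family members and targets 1 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.365). Of 7 CDK inhibitors 1 rose, 2 adjusted over the list alone (camera adjusted p = 0.419). Of 37 interferon response genes 5 rose and 1 fell, 5 and 2 adjusted over the list alone, with SAMD9 at 0.48. The list was not called (camera adjusted p = 0.682). Against pooled controls CDKN2B at 0.64 and SAMD9 at 0.25 lost their calls (adjusted p = 0.0744 and 0.325; ranges over alternatives 4.19e-11 to 0.0744 and 1.36e-08 to 0.325), and SAMD9 was lower in the controls of the TP63 experiment than in those of the MYC experiment (-0.47). Markers of fibroblasts, melanocytes, immune cells and endothelium were not called, with list medians of at most 0.03 in size.

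After TP63 siRNA 1615 of 19622 genes and unnamed probes passed limma's test with Benjamini-Hochberg adjustment, 878 higher and 737 lower, and 134 reached 1.5-fold and 25 reached 2-fold. These are 8.23% of all features, and the share of mitosis genes that passed was about the same. The number was 879 without TP63 siRNA replicate 1, 999 without replicate 3 of its controls and 1070 without replicate 1 of its controls. Of the 28 lists 14 were called with camera's preset correlation, against 0 with an estimated correlation (lowest adjusted p = 0.137), and other groupings of the same 6 replicates gave 4 to 14 called lists. These groupings too keep part of the real effect.

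The effects of both siRNAs were set against each other across all 19622 genes and probes. Genes higher after either siRNA overlapped in 401 cases where 118 were expected from independent sets (Fisher's exact test, p = 1.87e-127), and genes lower after either in 427 cases where 99.3 were expected (p = 1.5e-186). TNFSF15, CLIC3, IVL, H2AC6, H2BC12 and H2BC5 were among those higher after both, and MYC, RRM1, IMPDH2, IARS1 and PHB2 among those lower after both. In every control replicate these named risers lay below the untransfected reference, and MYC, RRM1, IMPDH2 and IARS1 lay above it. Genes higher after MYC siRNA and lower after TP63 siRNA numbered 92 where 98.7 were expected (p = 0.508), and 71 were lower after MYC siRNA and higher after TP63 siRNA where 118 were expected (p = 4.96e-07). The log2 fold changes correlated across genes at r = 0.379 (Spearman 0.34), with a covariance of 0.00956 against 4e-06 in simulated unchanged groups. The simulated replicates were drawn independently, so their small covariance was set in advance and does not test this likeness. The experiments share no control replicate, and genes are not independent replicates. These Fisher p-values treat genes as independent. Set against the reference in place of their controls, both siRNAs correlated across genes at r = 0.212. Among genes within 0.05 of the reference in both control groups both effects still correlated at r = 0.274. A response to the control siRNA that both targeting siRNAs lack may thus contribute to the overlap, and how much was not tested.

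The difference between both effects was tested directly, and 2247 genes and probes passed (limma, Benjamini-Hochberg), 1343 less lowered or more raised by TP63 siRNA and 904 the other way. FST, DKK3 and PTHLH, the gene of parathyroid hormone-related protein, rose by 0.98, 0.98 and 1.03 after MYC siRNA and fell by 1.30, 1.09 and 0.76 after TP63 siRNA. Their differences of effect, TP63 minus MYC, were -2.28, -2.07 and -1.78 (SE 0.13, 0.090 and 0.14; adjusted p = 1.56e-05, 2.47e-06 and 5.26e-05, n = 3 per group). THBS1, CCL2 and CA2 differed by -2.53, -2.01 and -1.98. CCL2 lost its call with scaling by the median absolute deviation (adjusted p = 0.0625), without control replicate 2 of the MYC experiment (adjusted p = 0.0513), without MYC siRNA replicate 2 (adjusted p = 0.0563) and without control replicate 1 of the TP63 experiment (adjusted p = 0.0544; range over alternatives 2.11e-08 to 0.0625). FOXM1, TYMS, TPX2, CEP55 and H4C3 differed by 1.41, 1.40, 1.38, 1.35 and 1.32, and ELF3 by 1.40.

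By list, the difference between both effects was called for mitosis genes, of which 34 of 37 differed and 35 adjusted over the list alone (camera adjusted p = 1.95e-37; adjusted p = 0.0407 with an estimated correlation). Hemidesmosome and basement membrane genes were lower relative to control after TP63 siRNA than after MYC siRNA in 7 of 17 cases, also 7 adjusted over the list alone (camera adjusted p = 1.56e-08; adjusted p = 0.0308 with an estimated correlation). TGF-beta, matrix and mesenchymal genes differed in the same direction in 10 of 31 cases, 13 against 1 adjusted over the list alone (camera adjusted p = 1.15e-06; adjusted p = 0.0112 with an estimated correlation). Of 25 reported p63 targets 7 differed in that direction, 9 adjusted over the list alone (camera adjusted p = 2.62e-05; adjusted p = 0.0348 with an estimated correlation). Of 21 p53 family members and targets 6 did and 1 differed the other way, 11 and 1 adjusted over the list alone (camera adjusted p = 3.23e-05; adjusted p = 0.0194 with an estimated correlation). Of the 28 lists 14 were called with the preset correlation, and these 5 were the ones called with an estimated correlation. Ribosome biogenesis genes were less lowered by TP63 siRNA in 7 of 26 cases, 13 adjusted over the list alone (camera adjusted p = 3.89e-06; adjusted p = 0.324 with an estimated correlation). Interferon response genes were less raised by TP63 siRNA in 10 of 37 cases, 18 against 1 adjusted over the list alone (camera adjusted p = 7.01e-10; adjusted p = 0.081 with an estimated correlation). The difference was not called for cytosolic ribosomal proteins, aminoacyl-tRNA synthetases or heat shock and chaperonin genes (camera adjusted p = 0.405, 0.775 and 0.0818).

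Control siRNA was also compared with the untransfected reference, in the mean of all 6 control replicates. The chemokine genes CCL2, CXCL1 and CXCL8 rose by 1.97, 1.91 and 1.12, and the transcription factor NFE2L3, DCBLD2 and THBS1 rose by between 0.93 and 1.04. IVL fell by 1.65 (SE 0.13, n = 6; limma, adjusted p = 3.2e-05), the keratin gene KRT4 by 1.36 and CLIC3 by 1.35, and ID3, the lipid synthesis regulator SREBF1 and CDKN2B fell by 0.97, 0.96 and 0.81. In total 8139 of 19622 genes and probes passed, 3718 higher and 4421 lower, but 77 reached 1.5-fold. This test is the ratio against 0 and leaves out the spread of the reference RNA itself, and the labels do not say whether reference cells were seeded or treated with reagent alongside. Of 25 EGFR ligands and inflammatory genes 16 rose and 1 fell, 17 and 2 adjusted over the list alone (camera adjusted p = 0.000129; adjusted p = 0.45 with an estimated correlation). Of 37 mitosis genes 26 rose, 28 adjusted over the list alone (camera adjusted p = 2.02e-09; adjusted p = 0.322 with an estimated correlation). Of the 28 lists 12 were called with the preset correlation and 0 with an estimated correlation.

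The control transfections of both experiments were compared with each other. PPDPF was higher in the controls of the TP63 experiment by 0.33 (SE 0.039, n = 3 per group; limma, adjusted p = 0.0081), a call lost without replicate 1 of those controls (adjusted p = 0.0546; range over alternatives 1.82e-12 to 0.0546). The scaffold gene IQGAP1 had a mean log2 difference of -0.69 (SE 0.058, adjusted p = 0.00113) over probes that went opposite ways, at -1.82 (adjusted p = 9.86e-06) and 0.44 (adjusted p = 0.135), so no direction is given for it. In all 62 genes and probes differed, 14 higher and 48 lower in the controls of the TP63 experiment. The number fell to 8, 35 and 26 without replicates 1, 2 and 3 of the controls of the TP63 experiment and to 13 without replicate 1 of those of the MYC experiment. Of the 28 lists 4 were called with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.441), the histone list among them. Hemidesmosome and basement membrane genes were higher in the controls of the TP63 experiment, with a median of 0.04 against -0.03 for the TP63 siRNA effect. None of the 17 passed, and 3 were higher adjusted over the list alone (camera adjusted p = 0.0309; adjusted p = 0.595 with an estimated correlation). Mitosis genes were also higher, with a median of 0.06 against -0.03 for the TP63 siRNA effect, 1 of 37 passing, also 1 adjusted over the list alone (camera adjusted p = 0.0126; adjusted p = 0.917 with an estimated correlation). Interferon response genes were lower, with a median of -0.05, 1 of 37 passing and 3 adjusted over the list alone (camera adjusted p = 0.0113; adjusted p = 0.714 with an estimated correlation). All 3 calls were lost with Cy3 arrays alone (adjusted p = 0.406, 0.0551 and 0.0667) and with Cy5 arrays alone (adjusted p = 0.196, 0.165 and 0.105). The hemidesmosome and mitosis calls were also lost with scaling by the median absolute deviation (adjusted p = 0.0566 and 0.0584) and with the first dye swap alone (adjusted p = 0.22 and 0.178), and the hemidesmosome call with single probes (adjusted p = 0.113). Without control replicate 3 of the MYC experiment the hemidesmosome and interferon calls were lost (adjusted p = 0.203 and 0.0807), as they were without control replicate 3 of the TP63 experiment (adjusted p = 0.23 and 0.0867). The mitosis call was lost without control replicate 2 of the MYC experiment (adjusted p = 0.513) and without control replicate 1 of the TP63 experiment (adjusted p = 0.108). Over alternatives the ranges were 0.00573 to 0.406, 0.00145 to 0.513 and 0.000524 to 0.105 for the hemidesmosome, mitosis and interferon lists. Experiment and any batch cannot be told apart in this comparison.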

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

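The splits of the samples reported here were planned before their results were seen.

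The controls of the TP63 experiment had higher log2 ratios to the reference than those of the MYC experiment for EIF4A1 (0.61), G3BP2 (0.55), RAD23B (0.50), IER3IP1 (0.38), PPDPF (0.33) and PTTG1 (0.31). They had lower ones for ZNF24 (-0.69), SGO2 (-0.64), USP40 (-0.52), KIF21A (-0.52) and SAMD9 (-0.47). IQGAP1 had a mean difference of -0.69 over probes that went opposite ways, at -1.82 and 0.44. These genes stood out because both groups received a non-targeting siRNA, and with them 62 genes and probes passed limma's test of the difference. Of these 12 genes 11 lost the call without at least 1 replicate, and IQGAP1 kept it: 9, 3 and 6 were lost without replicates 1, 2 and 3 of the controls of the MYC experiment and 11, 3 and 8 without those of the TP63 experiment. With either dye swap alone EIF4A1, G3BP2, SGO2 and SAMD9 also lost their calls, and with the second alone RAD23B, PTTG1, USP40 and KIF21A as well. G3BP2, RAD23B, SGO2 and SAMD9 lost them with Cy3 arrays alone, and EIF4A1 and SGO2 with robust moderation (limma, adjusted p = 0.0507 for each). The count was 13 without replicate 1 of the MYC experiment's controls, and 8, 35 and 26 without replicates 1, 2 and 3 of the TP63 experiment's controls. Of the 10 splits of the 6 control replicates 1, the real one, gave 62 or more genes, and the highest other gave 0; 10 splits are too few for a share under 0.05. No biological explanation was tested, and experiment and batch cannot be told apart here.

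FOXM1, TYMS, TPX2, CEP55 and H4C3 fell after MYC siRNA and did not pass the test after TP63 siRNA, while FST, DKK3 and PTHLH moved in opposite directions. They stood out because the effects of both siRNAs differed, with 2247 genes and probes past limma's test of the difference. Of 100 splits within both experiments, drawn from 200, 3 gave as many genes, the real one included, and the highest other gave 3488. The 9 drawn splits that kept or turned the MYC groups gave 1379 to 3488 genes, among which the real one ranked 3 from the top, and those that broke them gave at most 146. The share was thus set by how rarely the MYC groups were drawn, and these splits do not decide whether the count of 2247 is beyond chance. Large counts followed the MYC groups however the TP63 replicates were grouped.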

How the results depend on the processing

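Replacing single outlying values was the 1 alternative chosen after the result was seen. MYC mRNA after MYC siRNA kept its direction and call in all alternatives run (-0.49 to -0.43 without single replicates). MYC mRNA after TP63 siRNA lost its call when only the 2 groups compared entered the fit (-0.43, adjusted p = 0.0623; range over alternatives 1.02e-07 to 0.0623; -0.53 to -0.31 without single replicates). TP63 mRNA after TP63 siRNA gained one there (-0.18, adjusted p = 0.047) and with 48 arrays (-0.18, adjusted p = 0.0136; range 0.0136 to 0.511; -0.20 to -0.14 without single replicates). TP63 mRNA after MYC siRNA lay between -0.03 and 0.12 without single replicates. Gene counts for MYC siRNA were 3195 at adjusted p under 0.01, 448 at 1.5-fold, 94 at 2-fold and 4213 to 4853 without single replicates. Those for TP63 siRNA were 999 with the second dye swap, 826 with Cy3 arrays, 743 at 0.01, 134 and 25 at 1.5-fold and 2-fold, 2979 with 48 arrays, and 879 (without TP63 siRNA replicate 1) to 1468. The difference of effects gave 1268 with Cy3 arrays, 1092, 368 and 76 at the stricter thresholds, 3665 with 48 arrays and 1670 to 2220. The controls of both experiments differed in 143 genes with scaling by the median absolute deviation, 259 with quantile normalization, 31 and 21 with the first and second dye swap, 193 and 954 with Cy3 and Cy5 arrays, 13, 11 and 0 at the stricter thresholds, 1117 with 48 arrays, and 8 (without control replicate 1 of the TP63 experiment) to 89 (without control replicate 2 of the MYC experiment). Control siRNA against the reference gave 4931, 77 and 10 at the stricter thresholds and 5882 to 7447 without single replicates. Stricter thresholds call fewer genes by construction, and with 48 arrays (correlation 0.0357 within an extract) arrays count almost as independent replicates; for the other changes the cause was not tested. The correlation of both effects was 0.461 with quantile normalization and 0.32 to 0.411 without single replicates (jackknife SE 0.0782). Called lists numbered 1 and 0 with an estimated correlation, and 18 to 19 (MYC) and 13 to 15 (TP63) without single replicates. Cytosolic ribosomal proteins over the reference reversed with Cy5 arrays alone (median -0.16, adjusted p = 0.0146), where dye effects remain. With the replicate number as a block 5950 genes passed for MYC siRNA (4994 shared), 2181 for TP63 siRNA (1511 shared) and 2896 for the difference (2083 shared). In the MYC experiment deviations of same-numbered replicates correlated at -0.0507, 0.333 and 0.11, so pairing was not shown. After TP63 siRNA COL17A1, ITGA6, SAMD9 and CDKN2B lost calls against pooled controls (adjusted p = 0.0871, 0.227, 0.325 and 0.0744), as EGFR did by single probes (0.0511). With 1 dye swap or dye CHORDC1, FBL, RRM1, CCNA2, ITGA6, OCLN, ADM and JAG1 lost calls after TP63 siRNA (highest adjusted p = 0.0559, 0.101, 0.0615, 0.102, 0.156, 0.0608, 0.0642 and 0.0843) and IL1RN after MYC siRNA (0.0757), as did ASNS after TP63 siRNA with only the 2 groups compared (0.0669). Over all alternatives for named genes other than MYC and TP63, the losses above included, 3613 results kept and 81 lost the call. For lists the numbers were 1165 and 112. Filters on missing values could move nothing, since 0 values were missing. Each of both filters still adds 169 kept results for genes to these numbers, and further ones for lists. Signal over background is unknown here, so how far dim spots limit these calls is open.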

Other observations

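The tests of shared control noise, of fewer cells in S phase, of cross-hybridisation and of a response to any siRNA were chosen only after the result was seen, as were the gene families named here; the other tests were written down before their results were seen.

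Of 68 mitochondrial ribosomal protein genes 62 fell and 1 rose after MYC siRNA, with a median of -0.34 (camera adjusted p = 1.06e-31 over 20 tests of families; adjusted p = 0.00129 with an estimated correlation). After TP63 siRNA 10 fell and 4 rose (adjusted p = 0.184 with an estimated correlation), and the difference between both effects passed (adjusted p = 0.00219 with an estimated correlation). Of 30 spliceosomal snRNP protein genes 21 fell and 1 rose after MYC siRNA (adjusted p = 0.0383 with an estimated correlation), and of 17 nuclear pore genes 13 fell and 1 rose (adjusted p = 0.1 with an estimated correlation).

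Of the 10 splits of the 6 replicates of the MYC experiment 1, the real one, gave 5273 genes, and the highest other gave 0; for called lists 1 split gave 18, and the highest other gave 12. In the TP63 experiment 1 split gave 1615 genes, and the highest other gave 0; for called lists 2 splits, the real one included, gave 14, so the highest other was 14. There 10 splits are too few for a share under 0.05. In the TP63 experiment, where the numbers may pair the samples, the real split parts 3 pairs. The other splits that part 3 pairs gave 0 genes and 8, 10 and 11 lists. Camera with its preset correlation called lists in every split of both experiments. Each other split mixes knockdown and control replicates unevenly, so part of the real effect remains in it. The splits therefore do not show how often camera calls unchanged lists, and that share stays unknown here.

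IVL, CLIC3 and CDKN2B fell in control siRNA against the untransfected reference and rose after both targeting siRNAs, while CCL2 and THBS1 rose in the controls and fell after TP63 siRNA. After MYC siRNA THBS1 lay further above the reference, at 1.88, 1.63 and 1.92 against 0.64, 0.47 and 0.86 in its controls. CCL2 stayed above the reference there, at 3.1, 3.0 and 1.6, so these 2 genes do not show a response that both siRNAs lack. Across genes the TP63 effect correlated at r = -0.469 (spread 0.016) with control over reference in the MYC experiment, which shares no library with it. This argues against noise of shared controls. Spreads here and below are SDs over resampled genes, not over replicates. Without control replicate 3 of the TP63 experiment r was -0.34 (spread 0.019), against an outlying control library as the source. Among genes within 0.05 of the reference in both control groups both effects still correlated at r = 0.274 (spread 0.022), against a response to the control siRNA as the whole source of their likeness. Of TP63 siRNA calls at least 0.1 from the reference in the MYC experiment's controls, 658 of 758 ran opposite to those controls. For MYC siRNA calls and the TP63 experiment's controls it was 1600 of 2032. Set against the reference in place of their controls, both siRNAs correlated across genes at r = 0.212. A response to the control siRNA that both targeting siRNAs lack may contribute, and how much was not tested.

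H2BC5, H2AC6, H2BC12 and H1-2 rose after MYC siRNA while RRM2, TYMS and MCM10 fell. Of 46 replication-dependent histone genes 22 rose and 8 fell, among them H4C3. In control siRNA over the reference 26 of the 46 were lower and 0 higher. If fewer cells in S phase lowered all of them, their median would lie below 0. It was 0.11 (spread 0.045), above 0 by more than its spread. It was not above the bound of 0.1 by more than its spread, so that bound leaves the question open. The 22 rises past limma's test against 8 falls argue against a loss of S phase cells that lowered all of these genes. For the 8 genes that fell it stays possible. A version of this test with a bound on the number of genes that rose would have excluded the explanation. Its bound was chosen after that number was known, so it was dropped, and the counts given here were likewise known beforehand. Cross-hybridisation among H2A and H2B probes may add to the pattern, but it would not reach the 11 H1, H3 and H4 genes that rose. Among all 19622 features 2629 rose, so some such rises would be found in any set of genes. The median was highest for H2B and H2A genes, at 0.30 and 0.16, against 0.11 for H3, 0.02 for H1 and -0.01 for H4. How much of the net rise cross-hybridisation makes is thus open. By class 2 of 6 H1, 4 of 7 H3 and 5 of 12 H4 genes rose, while 1, 1 and 5 fell. Probes within each of these classes may also read several copies, which this count does not address.

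IFIT1, IFIT2 and TRIM22 rose after MYC siRNA with 24 of 37 interferon response genes, with a list median of 0.16. In control siRNA over the reference the list median was -0.02 (-0.0165, spread 0.0095), which argues against a response to any transfected siRNA. Without any 1 of the MYC siRNA replicates the lowest list median was 0.149, against a single replicate as the source. A response to this siRNA's sequence and an effect of lower MYC may each contribute, and the design, with 1 siRNA condition per target in the labels, cannot separate them.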
